A study of Mus musculus with 12 samples.

How the data were processed

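Hearts of female mouse embryos at embryonic day 10.5 were pooled by genotype, 20 hearts to a pool and 3 pools per genotype, and each pool was split into an RNA library and a footprint library. Per the labels' protocols, hearts were snap frozen one by one, carcasses were genotyped for Sry, Ddx3x and Tnnt2-Cre, and pools were lysed in a commercial buffer. RNA libraries were made from 0.75 µg of heat-fragmented total RNA. Footprint libraries were made from 7.1 to 9.0 µg of total RNA digested with RNase I, which leaves the RNA covered by ribosomes. Both kinds went through ribosomal RNA depletion, adapter ligation, reverse transcription and PCR. Nothing in the labels says that unique molecular identifiers were counted, so tests on counts of single pools take reads as independent and may understate the error. The intervals of log2 fold changes also hold the spread between pools.

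Per the labels' protocols, the authors had reads processed against mm39 with a service provider's own pipeline and feature counter. The aligner, the annotation release, the strand setting and the part of each transcript that was counted are not given in the sources used here. The deposited table holds raw read counts per gene for the 12 libraries, which the authors did not normalize. The authors' RPM columns, scaled to the reads in genes, were read only to check the library totals. The authors' occupancy columns are a ratio of footprint to RNA coverage, and 85.6% of their values lay within 5% of the ratio of the 2 RPM values where both counts exceeded 50. The deposited log2 fold changes and adjusted p-values are the authors' own, from DESeq2 for RNA per the labels' protocols and for footprints per the file headers, and the test behind their occupancy p-values is not given in the sources used here. They were used for comparison only.

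The table listed 21783 genes. A pool's cells for a gene were blank unless its RNA or its footprint count was at least 11, so a blank hides at most 10 counts in each assay. The 17165 genes with values in all 6 pools were tested, and the 4618 with blanks were left out of the tests. Gene IDs were matched to the GENCODE vM39 annotation of GRCm39, which is the mm39 assembly, and 21594 were found and 189 were not. A further check found 15 entries sharing 7 symbols. Totals per library were 14.7 to 19.9 M counts for RNA and 7.31 to 14.3 M for footprints. The most abundant gene was H19 in every RNA library (1.56 to 2.16% of counts) and the non-coding RNA Rmrp in every footprint library (3.69 to 6.95%). The 10 most abundant genes took 6.71 to 9.27% of RNA counts and 15.1 to 18.9% of footprint counts. Reads of near-identical copies (globins, histones, ribosomal protein pseudogenes, Ddx3x and Ddx3y) and of overlapping or antisense genes could have been split or shared by the authors' counting.

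Groups were taken from the labels. RNA and footprint libraries were each tested 3 against 3 with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, robust fit) after TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15). Occupancy was tested as the interaction of genotype and assay in one model over the 12 libraries, for genes that passed the filter in both assays. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Levels are TMM-scaled CPM, scaled within each assay, as mean ± SD over 3 pools. Log2 ratios of footprints to RNA per pool were taken after TMM scaling of the 12 libraries together, with a prior count of 1, so their levels are offset from those of the CPM. The pools are separate sets of hearts. The tests of 3 against 3 cannot give an exact permutation p under 0.1 for a single gene. The common dispersion of the occupancy fit covers both assays. The RNA and the footprint library of 1 pool come from the same hearts, and their deviations from the group means correlated by 0.05 to 0.59 over 8641 genes, so the fit with the pool as a block is given beside the occupancy results where it changes them.

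A total of 31 gene lists (pathways, cell type markers and complexes) were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Lists with fewer than 5 tested members were not tested. Called members were counted over all genes and adjusted over the list alone. With an estimated correlation the p53 list in RNA kept its call, and no other list did in any of the 3 comparisons. The fry test of limma, which does not set list members against other genes, was run beside camera. In RNA the p53 list (fry adjusted p = 0.00457) and the mRNAs reported as sensitive to DDX3X (fry adjusted p = 0.00955) passed it. No other list passed it in any of the 3 comparisons. For 5′ UTR features 1 coding transcript was taken per gene from the annotation, and GC content and RNAfold energy (ViennaRNA 2.7.2) were computed over at most 200 bases before the start codon in the 13606 tested genes with a 5′ UTR of at least 20 bases. The top and bottom quintile by each feature were tested with camera on the occupancy contrast. Intron length and 3′ UTR length were added as features after seeing the data. Positions are 1-based.

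Genes named in the text follow a rule fixed before the data were examined, as were the groups, tests, gene lists and most alternatives. The rule takes Ddx3x, then in each comparison up to 6 called genes with the largest rise and 6 with the largest fall whose pools do not overlap and whose mean reaches 10 CPM, without predicted symbols. It adds up to 4 called members of each list, up to 2 further members of each list with an adjusted p under 0.05, and Ddx3y, Xist and Tnnt2 as label checks. Uty, Eif2s3y, Kdm5d, Kdm6a, Afp, Hbb-y, Hba-x and Gm10762 and the genes listed among blanks were chosen after their values were seen. Some genes that the rule takes, and a sequence, are not reported here.

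The tests were checked on simulated counts drawn from the real means and library sizes. Of 100 genes changed by 1 on the log2 scale the RNA test recovered 64% and of 100 changed by 0.5 it recovered 50%, with 9 false calls among 123 over 17131 genes. The footprint test recovered 62% and 26% (8 false among 96, over 15243 genes), and the occupancy test 66% and 13% (11 false among 90, over 15239 genes).

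Alternatives covered DESeq2 1.42.0, RLE and upper quartile scaling, other count filters, leaving out abundant gene families, a fold threshold, each pool left out in turn, blocks by replicate number and by pool, all libraries in one model and limma on log2 ratios with a prior count of 1. Alternatives chosen after seeing the data were blanks set to 0 or 5, protein-coding genes only, both CM-KO pools with Y-linked reads left out together, and the Afp level of the pool as a covariate. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.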

Results

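Ribosome profiling and RNA-seq were carried out on hearts of female mouse embryos at embryonic day 10.5, when the looped heart grows its chambers and trabeculae. DDX3X is an X-linked DEAD-box RNA helicase with a role in translation initiation, and the series asked how it acts on structured mRNAs of the heart. WT embryos carried floxed Ddx3x alleles, and in CM-KO embryos Ddx3x was deleted in cardiomyocytes with Tnnt2-Cre. Each genotype gave 3 pools of 20 hearts, and each pool gave 1 RNA library and 1 library of ribosome-protected footprints (RPF), so that 12 libraries formed 4 groups of 3. The RNA libraries held 14.7 to 19.9 M counts in genes and the footprint libraries 7.31 to 14.3 M. At these depths the median half-width of the 95% confidence interval of a log2 fold change was 0.23 for RNA, 0.32 for footprints and 0.40 for the footprint-to-RNA ratio.

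The targeted gene Ddx3x (chromosome X, 13146705 to 13160293, GRCm39) was read first in every library. WT RNA pools 1, 2 and 3 gave 4348, 5608 and 6227 Ddx3x counts and CM-KO pools 1, 2 and 3 gave 4418, 3251 and 3781. In the footprint libraries the Ddx3x counts were 6179, 4946 and 6777 in WT and 4406, 5456 and 6929 in CM-KO. After scaling for library size, Ddx3x RNA was 303 ± 8.95 CPM (TMM-scaled) in WT and 239 ± 36.0 in CM-KO (mean ± SD, n = 3), a log2 fold change of -0.34 (SE 0.10, adjusted p = 0.0883, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ddx3x footprints were at 633 ± 34.6 and 528 ± 33.7 CPM (log2 fold change -0.26, SE 0.08, adjusted p = 0.35). The CM-KO pools lay below all WT pools in both assays, and neither difference passed the threshold. In 1 assay, chance keeps the genotypes from overlapping, in either direction, for 10% of genes. Over 19 alternative settings the RNA change ran from -0.48 to -0.27 with adjusted p from 0.00589 to 0.328, and it passed without CM-KO pool 1 (-0.48, adjusted p = 0.00941). The authors' deposited table lists a Ddx3x RNA log2 fold change of -0.35 with an adjusted p of 0.00739. The libraries are of whole hearts, which also hold cells outside the cardiomyocyte lineage. The part of the gene that was counted is not given in the sources used here.

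Markers of sex and of other tissues differed between pools of 1 genotype. Xist, the RNA of the inactive X chromosome, gave 4322 to 8219 counts in every RNA library, with a log2 fold change of -0.07 (adjusted p = 0.916). Ddx3y, the Y-linked copy of Ddx3x, had 2, 2 and 0 counts in WT RNA pools 1 to 3 and 106, 64 and 4 in CM-KO. Its footprint counts were 15, 21 and 19 in WT and 69, 75 and 24 in CM-KO. The Y-linked histone demethylase gene Uty gave 174, 108 and 11 RNA counts in CM-KO pools 1 to 3 and was blank in every WT pool, where a blank hides at most 10 counts in each assay. Afp, the yolk sac and fetal liver gene for alpha-fetoprotein, stood at 49.7, 259 and 306 CPM in WT RNA pools 1 to 3 and at 90.2, 20.2 and 220 in CM-KO. Tnnt2, whose promoter drives the Cre, had a log2 fold change of 0.11 in RNA (adjusted p = 0.62) and 0.31 in footprints (adjusted p = 0.368).

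**Figure D1:**
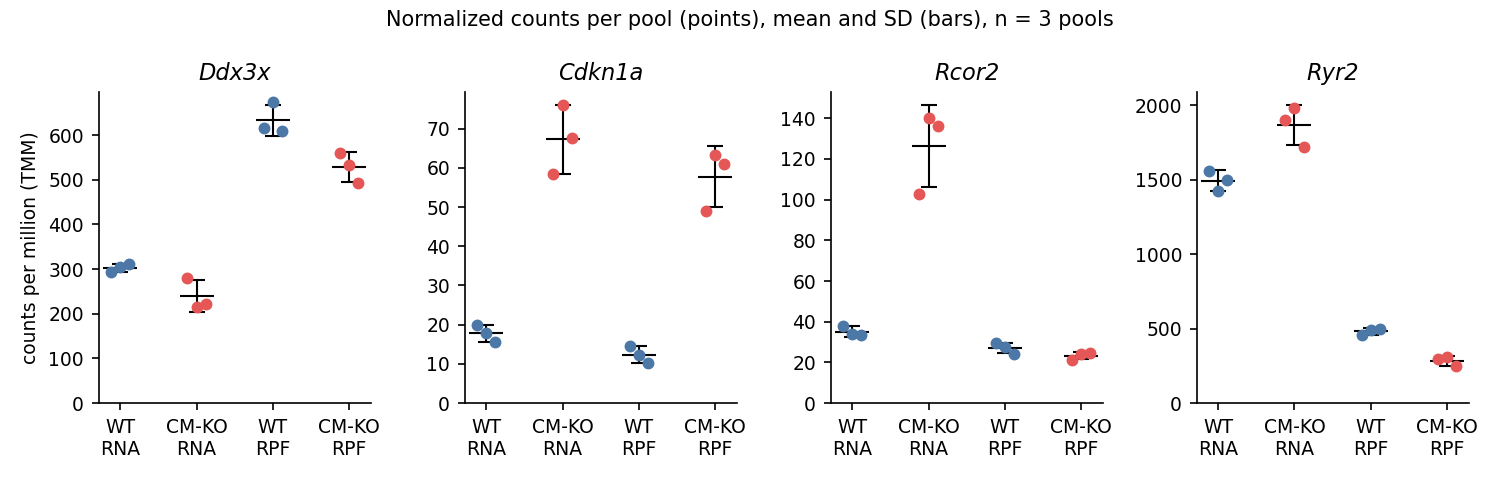
TMM-scaled CPM of Ddx3x, Cdkn1a, Rcor2 and Ryr2 in each of the 12 libraries (points), with the mean and SD of 3 pools (bars), for WT (blue) and CM-KO (red) in RNA and footprint (RPF) libraries. Cdkn1a was higher in CM-KO in both assays, with means of 17.8 and 67.3 in RNA, while Rcor2 was higher in RNA (35.1 and 126) with footprints of 27.0 and 23.4, and Ryr2 footprints were lower in CM-KO (481 and 285).

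The first comparison asked which transcripts differ in abundance between CM-KO and WT hearts. Target genes of the stress-induced transcription factor p53 were higher in CM-KO. Cdkn1a (chromosome 17, 29309936 to 29319701), which encodes a cyclin-dependent kinase inhibitor that halts the cell cycle, rose from 17.8 ± 2.14 to 67.3 ± 8.77 CPM (mean ± SD, n = 3), a log2 fold change of 1.92 (SE 0.11, adjusted p = 4.68e-05). Trp53inp1 (chromosome 4, 11156412 to 11175230), a p53-induced regulator of apoptosis and autophagy, rose from 29.0 ± 0.822 to 88.7 ± 9.39 (log2 fold change 1.61, adjusted p = 2.95e-05). The TNF receptor family gene Eda2r (1.17), the antiproliferative gene Btg2 (0.84), the AKT inhibitor gene Phlda3 (0.84) and the RNA-binding protein gene Zmat3 (0.59) rose as well, with adjusted p from 0.00036 to 0.00131. Of 30 p53 targets tested 17 rose, or 20 when adjusted over the list alone, and the median log2 fold change of the list was 0.45 (camera adjusted p = 2.24e-38). That list held with an estimated correlation (adjusted p = 0.0477). Its median deviation from the mean of the RNA libraries lay between -0.27 and -0.23 in the WT pools and between 0.20 and 0.32 in the CM-KO pools. In CM-KO pools 1 and 2 the Y-linked transcripts above were present as well, while pool 3 held few of them.

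Beyond p53 targets, the largest rises were in Rcor2 (chromosome 19, 7241690 to 7252591), a corepressor of the REST and LSD1 complex, from 35.1 ± 2.58 to 126 ± 20.1 CPM (n = 3, log2 fold change 1.85, adjusted p = 5.62e-05). Ppp1r3c (chromosome 19, 36708523 to 36714070), which targets a protein phosphatase to glycogen, rose from 65.7 ± 8.49 to 205 ± 29.8 (1.65, adjusted p = 0.000248). The homeobox gene Irx1 (1.42, adjusted p = 0.000438) and the zinc finger gene Zfp365 (1.41, adjusted p = 0.000948) followed. Among the falls, Myoz2, which encodes a calcineurin-binding protein of the Z-disc, fell from 36.0 ± 5.01 to 17.5 ± 1.35 CPM (n = 3, log2 fold change -1.04, adjusted p = 0.000948). Fbxl22 (-0.92), an F-box protein of the sarcomere, Cav3 (-0.87), the muscle caveolin, and Rnf207 (-0.90), a RING finger protein of heart muscle, fell with adjusted p from 0.000586 to 0.032. Hjv, which encodes the BMP co-receptor hemojuvelin, fell by 0.97 on the log2 scale (adjusted p = 0.00636).

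Contractile and calcium-handling transcripts split in direction. Among 34 sarcomere genes 3 rose and 3 fell (5 and 5 adjusted over the list alone), with a list median of -0.06 (camera adjusted p = 0.0999, and adjusted p = 0.856 with an estimated correlation). At the preset correlation that list passed without WT pool 2 (-0.10, adjusted p = 0.00673) and without CM-KO pool 2 (-0.09, adjusted p = 0.00192). The chaperone gene Cryab (-0.63, adjusted p = 0.00567), the stretch-responsive muscle gene Smpx (-0.54, adjusted p = 0.00592) and the ventricular myosin light chain gene Myl2 (-0.51, adjusted p = 0.0154) fell, while the Z-disc gene Tcap rose (0.69, adjusted p = 0.0344). Of 30 calcium-handling, channel and junction genes 2 rose and 5 fell (4 and 8 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.0307, and adjusted p = 0.856 with an estimated correlation). Pln, the inhibitor of the sarcoplasmic calcium pump, fell from 204 ± 13.1 to 129 ± 20.3 CPM (n = 3, log2 fold change -0.67, adjusted p = 0.00705). Kcne1, a potassium channel subunit gene, fell by 0.77 (adjusted p = 0.00695), and Atp2a2, which encodes the pump itself, rose by 0.38 (adjusted p = 0.0253), as did the potassium channel gene Kcnh2 by 0.79 (adjusted p = 0.00516). The call of that list ended without WT pool 3 (adjusted p = 0.222) and without CM-KO pool 3 (adjusted p = 0.177).

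Of 28 genes of trabeculation and chamber growth 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 4.86e-05, and adjusted p = 0.56 with an estimated correlation). The natriuretic peptide genes Nppa (0.51, adjusted p = 0.00553) and Nppb (0.76, adjusted p = 0.00984) rose, as did the cell cycle activator gene Ccnd2 (0.59, adjusted p = 0.00213) and the growth factor gene Nrg1 (0.52, adjusted p = 0.0222), while the trabecular growth factor gene Bmp10 fell (-0.32, adjusted p = 0.0358). Among 30 cardiac transcription factor genes 2 rose (6 higher and 2 lower adjusted over the list alone), namely Srf (0.73, adjusted p = 0.00263) and Nkx2-5 (0.59, adjusted p = 0.018), with a list median of 0.02 (camera adjusted p = 0.528). Of 10 mRNAs reported as sensitive to DDX3X in other cell types 3 rose (5 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 2.39e-07, adjusted p = 0.0686 with an estimated correlation, and fry adjusted p = 0.00955). These 3 were Ccnd2, the casein kinase gene Csnk1e (0.62, adjusted p = 0.0023) and the polyamine synthesis gene Odc1 (0.48, adjusted p = 0.0107).

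Stress-response, blood and mitochondrial transcripts also differed. Among 32 genes of ATF4 and the integrated stress response 7 rose (12 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.37e-08, and adjusted p = 0.788 with an estimated correlation). They included Sesn2 (0.92, adjusted p = 0.00316), a stress-induced inhibitor of growth signalling, the mitochondrial folate enzyme gene Mthfd2 (0.65, adjusted p = 0.006) and Atf4 itself (0.37, adjusted p = 0.03). Of 26 erythroid markers 11 rose (20 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.31e-16, and adjusted p = 0.434 with an estimated correlation), among them the adult globin gene Hbb-bs (0.81, adjusted p = 0.0287) and the erythroid transcription factor gene Nfe2 (0.57, adjusted p = 0.0114). The erythroid median deviated by -0.35 to -0.03 in WT RNA pools and by 0.07 to 0.32 in CM-KO pools. All 9 mitochondrially encoded genes tested had values below 0 and 3 of them fell (8 adjusted over the list alone), with a median of -0.79 (camera adjusted p = 3.44e-12, and adjusted p = 0.434 with an estimated correlation). mt-Cytb, a subunit gene of the respiratory chain, fell by 0.97 (adjusted p = 0.0273) and mt-Nd1 by 0.79 (adjusted p = 0.016), and the mitochondrial median deviated by 0.07 to 0.85 in WT RNA pools and by -0.51 to -0.21 in CM-KO pools. The 17 liver, gut and yolk sac markers had a median of -0.75 (camera adjusted p = 0.0179, and adjusted p = 0.856 with an estimated correlation), with pool values from -0.68 to 1.07 in WT and from -1.31 to 0.65 in CM-KO. The call of these markers ended without WT pool 2 (-0.59, adjusted p = 0.0646), WT pool 3 (-0.36, adjusted p = 0.227), CM-KO pool 1 (-0.57, adjusted p = 0.138) or CM-KO pool 2 (-0.37, adjusted p = 0.121).

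In all, 750 of 17147 genes differed in RNA at an adjusted p under 0.05 in the edgeR quasi-likelihood test, 612 higher and 138 lower in CM-KO (81.6% higher, and 63.6% with upper quartile scaling). With a log2 fold change of at least 0.5 as well, 287 remained, 219 higher and 68 lower. The 3 pools of each genotype did not overlap for any of the 750 and for 21.7% of all genes tested, where chance gives 10%. The authors' deposited table lists 846 RNA changes at the same adjusted p, 689 higher and 157 lower, and 665 of them were among the 750 with the same sign. The count fell to 207 without WT pool 2, to 287 without CM-KO pool 2 and to 367 without CM-KO pool 3. It was 286 with the Afp level of the pool as a covariate, a setting chosen after seeing the data. The fit without both CM-KO pools that held Y-linked reads kept only CM-KO pool 3 and is given further below. Of the named RNA genes 31 of 66 passed with every pool left out in turn, Cdkn1a, Trp53inp1, Rcor2, Ppp1r3c and Myoz2 among them.

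**Figure D2:**
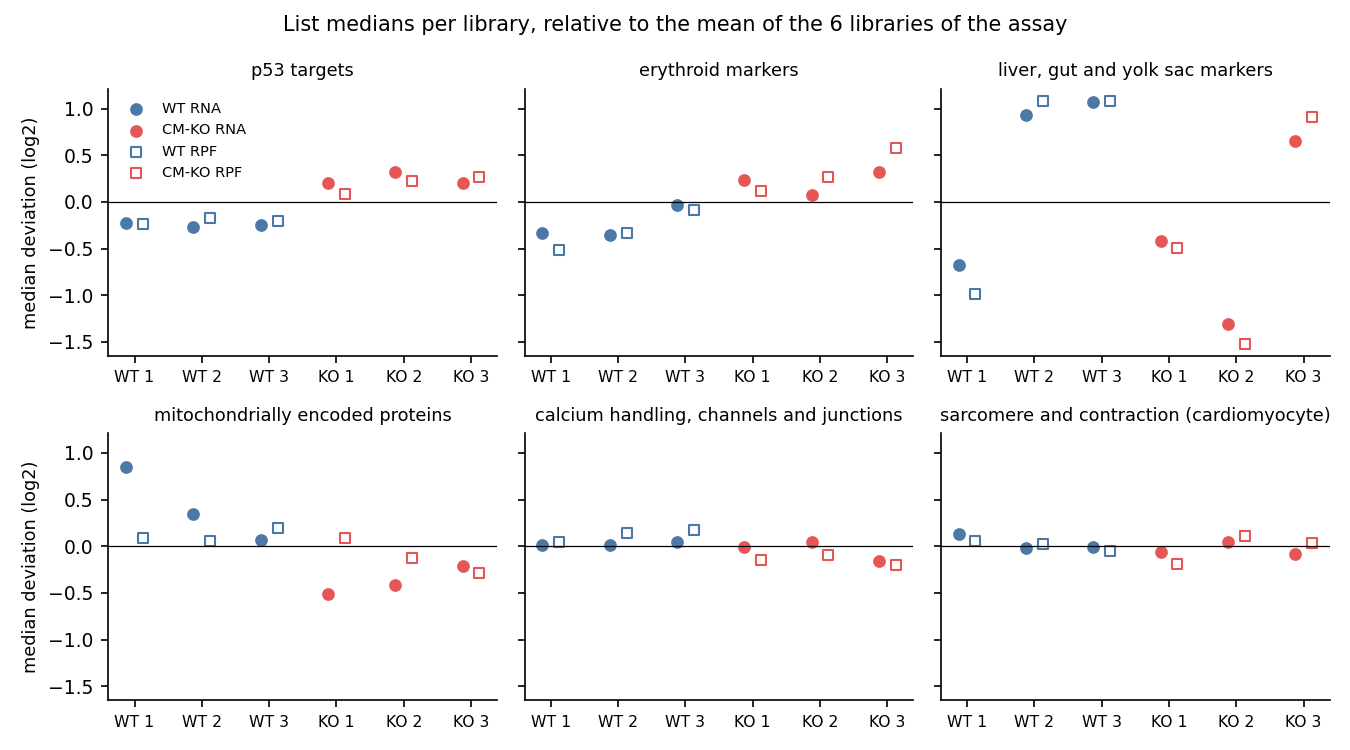
Median deviation of 6 gene lists in each library (log2, relative to the mean of the 6 libraries of the same assay), for RNA (filled circles) and footprints (open squares) in WT (blue) and CM-KO (red) pools. The p53 targets lay below 0 in every WT library and above 0 in every CM-KO library, while the liver, gut and yolk sac markers ranged from -1.31 to 1.07 in RNA with both genotypes on both sides of 0.

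The second comparison took footprint abundance, which holds changes of RNA and of ribosome occupancy together. Cdkn1a footprints rose from 12.4 ± 2.16 to 57.7 ± 7.75 CPM (mean ± SD, n = 3), a log2 fold change of 2.23 (SE 0.15, adjusted p = 0.000948, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Footprints of Eda2r (1.78, adjusted p = 0.011), of the matricellular growth factor gene Ccn2 (1.25, adjusted p = 0.0315) and of the endothelin gene Edn1 (1.03, adjusted p = 0.0207) rose too. The guidance cue gene Ntn1 fell from 56.1 ± 6.24 to 26.7 ± 0.508 (log2 fold change -1.07, adjusted p = 0.00509), the proprotein convertase gene Pcsk6 by 1.08 (adjusted p = 0.037) and Fbxl22 by 0.87 (adjusted p = 0.00625). Of 30 p53 targets 4 rose (17 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.44e-26, and adjusted p = 0.221 with an estimated correlation).

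Footprints of 3 of 30 genes of calcium handling, channels and junctions were lower in CM-KO. Ryr2 (chromosome 13, 11567988 to 12121870), which encodes the calcium release channel of the sarcoplasmic reticulum, fell from 481 ± 22 to 285 ± 31.7 CPM (n = 3, log2 fold change -0.76, SE 0.09, adjusted p = 0.0207). The calsequestrin gene Casq1 fell by 0.69 (adjusted p = 0.043), and Atp2a2 had a log2 fold change of -0.57 that missed the threshold (adjusted p = 0.0609). Adjusted over the list alone, 10 were lower and 1 higher, with a list median of -0.27 (camera adjusted p = 6.21e-16, and adjusted p = 0.221 with an estimated correlation). The footprints of the 34 sarcomere genes had a median of -0.03 (camera adjusted p = 0.688, and adjusted p = 0.941 with an estimated correlation, or -0.12 and 0.00589 at the preset correlation without CM-KO pool 2), with 1 fall, in Smpx (-0.46, adjusted p = 0.0395), and 1 higher and 2 lower adjusted over the list alone. Erythroid footprints had a median of 0.65 over 26 genes, of which 1 rose over all genes and 25 adjusted over the list alone (camera adjusted p = 5.98e-48, and adjusted p = 0.221 with an estimated correlation). The ATF4 list had a footprint median of 0.32 (camera adjusted p = 4.02e-11, and adjusted p = 0.475 with an estimated correlation), and the mitochondrially encoded genes one of -0.21 (camera adjusted p = 0.00047, and adjusted p = 0.475 with an estimated correlation).

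Footprints of 35 of 15249 genes differed, 13 higher and 22 lower, and 9 of these passed a log2 fold change of 1. The balance of directions depended on the setting. Here 37.1% were higher. That share was 57% of 172 with DESeq2, 55% of 80 with all 12 libraries in one model and 67% without CM-KO pool 1. The pools of the 2 genotypes did not overlap for 14.8% of all genes tested. The authors' deposited table lists 152 footprint changes at an adjusted p under 0.05, 88 higher and 64 lower, and holds all 35. The count was 1 without WT pool 2, 5 without WT pool 3, 4 without CM-KO pool 3 and 94 without CM-KO pool 1. Of the named footprint genes 1 of 21, Cdkn1a, passed with every pool left out in turn. The count was 5 with the Afp covariate. The fit without both CM-KO pools that held Y-linked reads kept only CM-KO pool 3, so its balance of directions rests on that pool.

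The third comparison asked where ribosome occupancy, the footprint-to-RNA ratio, differed between the genotypes, and the calls ran almost wholly one way. The log2 ratios were scaled over the 12 libraries together and the CPM within each assay. The level of a ratio therefore does not follow from the CPM, and a ratio of 0 does not mean equal CPM. For Rcor2 the log2 ratio of footprints to RNA fell from 0.01 ± 0.16 in WT to -2.02 ± 0.12 in CM-KO (mean ± SD, n = 3), a change of -2.04 (SE 0.16, adjusted p = 1.87e-06, edgeR quasi-likelihood test of the interaction of genotype and assay). Ppp1r3c fell from 0.38 ± 0.09 to -1.52 ± 0.02 (-1.89, adjusted p = 2.81e-06) and Irx1 from 0.03 ± 0.21 to -2.10 ± 0.12 (-2.15, adjusted p = 2.91e-05). Arrdc4 (-1.79), an arrestin that limits glucose uptake, Rhod (-1.43), a small GTPase of endosomes, and Bmt2 (-1.40), a sensor of S-adenosylmethionine in growth signalling, fell with adjusted p from 3.09e-05 to 0.000211. In each of these 6 genes RNA was higher in CM-KO while the footprint change missed the threshold.

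Occupancy also fell in genes of calcium handling, growth and cardiac transcription. On the log2 ratio, scaled over the 12 libraries together as above, Ryr2 fell from -1.24 ± 0.13 to -2.32 ± 0.01 (n = 3, change -1.07, adjusted p = 0.00116), Atp2a2 from 1.16 ± 0.06 to 0.22 ± 0.04 (-0.94, adjusted p = 0.0025) and Kcnh2 by 1.06 (adjusted p = 0.00577). Of the 30 genes in this list these 3 fell (5 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 5.9e-05, and adjusted p = 0.955 with an estimated correlation). Pdk1, which encodes a kinase that limits pyruvate use in mitochondria, fell by 1.05 (adjusted p = 0.00116). Of 30 cardiac transcription factor genes 2 fell (4 adjusted over the list alone), namely Srf (-1.01, adjusted p = 0.00484) and Irx4 (-0.91, adjusted p = 0.0136), with a median of -0.05 (camera adjusted p = 0.0608, and adjusted p = 0.955 with an estimated correlation). At the preset correlation it passed with the pool as a block (adjusted p = 0.0373) and without WT pool 3 (adjusted p = 0.0149), CM-KO pool 2 (adjusted p = 0.00708) or CM-KO pool 3 (adjusted p = 0.0135). Of 28 genes of trabeculation and chamber growth 2 fell, which were Ccnd2 (-0.81, adjusted p = 0.00407) and Cited1 (-0.86, adjusted p = 0.0193), and 2 when adjusted over the list alone. The median of that list was -0.07 (camera adjusted p = 0.0371, and adjusted p = 0.955 with an estimated correlation), and its call ended without WT pool 1 (0.026, adjusted p = 0.079), WT pool 2 (-0.03, adjusted p = 0.112) or CM-KO pool 1 (0.064, adjusted p = 0.759). Of the 10 mRNAs reported as sensitive to DDX3X elsewhere 2 fell, Ccnd2 and Csnk1e (-0.72, adjusted p = 0.00825), or 4 lower and 1 higher adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.000936, and adjusted p = 0.57 with an estimated correlation, or 0.0862 without CM-KO pool 1). The p53 targets had a median of -0.01, with 15 of 30 genes above 0 (camera adjusted p = 0.583), and 1 of them, Trp53inp1, fell (-0.93, adjusted p = 0.00514; 1 adjusted over the list alone).

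In total 128 of 15231 genes differed in occupancy, 127 lower and 1 higher, and 226 with the pool as a block, 127 of which were among the 128. Other settings gave 3 (limma on log2 ratios per pool), 29 (no count filter), 41 (RLE scaling), 59 (DESeq2), 248 (upper quartile scaling) and 282 (stricter filter). The single higher gene was the predicted gene Gm10762 (1.32, adjusted p = 0.0319), chosen after its values were seen, with footprints of 0.902 ± 0.184 and 2.27 ± 0.317 CPM (n = 3). A log2 change of at least 1 was reached by 30 of the 128. The pools did not overlap for any of the 128 and for 12.1% of all genes. The authors' deposited table lists 310 occupancy changes at an adjusted p under 0.05, 14 higher and 296 lower, and holds all 128. The count was 58 without WT pool 1, 13 without WT pool 2, 72 without CM-KO pool 1, 43 without CM-KO pool 2 and 9 without CM-KO pool 3. Rcor2, Ppp1r3c, Irx1, Bmt2 and Arrdc4 were the 5 of 20 named genes that passed with every pool left out in turn. The count was 39 with the Afp covariate. The fit without both CM-KO pools that held Y-linked reads kept only CM-KO pool 3 and is given further below.

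**Figure D3:**
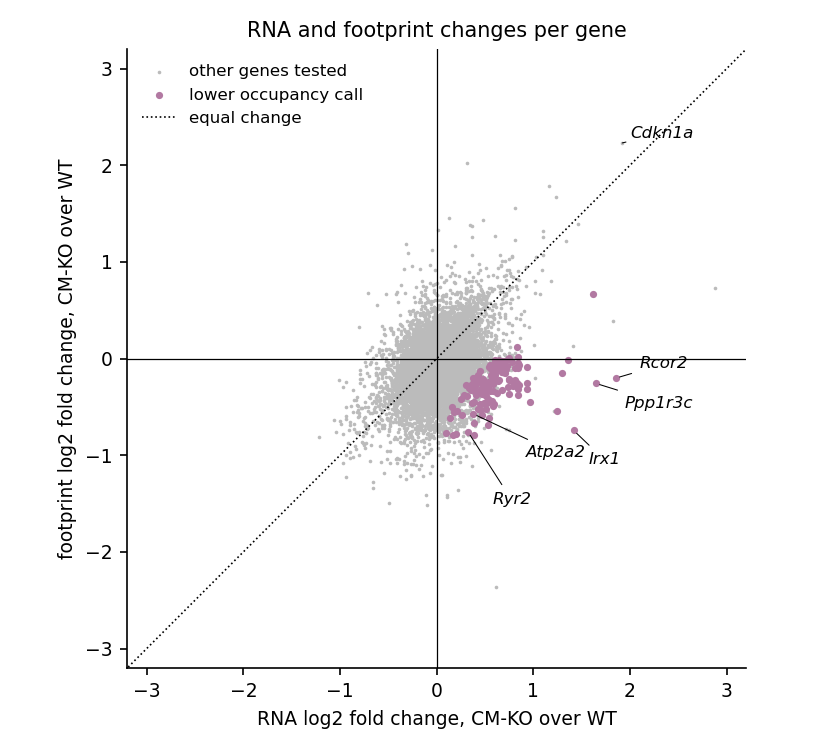
Log2 fold change of RNA (horizontal axis) and of footprints (vertical axis), CM-KO over WT, for the 15231 genes tested in both assays, with the 127 genes of lower occupancy in purple and equal change as a dotted line. The purple genes lie to the right of 0 in RNA (median 0.58), mostly below 0 in footprints (median -0.26), while Cdkn1a was higher in both.

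Most of the lower ratios went with more RNA. All 127 genes with lower occupancy had an RNA log2 fold change above 0, and 123 had a footprint log2 fold change below 0, with medians of 0.58 in RNA and -0.26 in footprints. Among the 127, 111 were also higher in RNA, and footprint falls passed the threshold for 6. RNA and occupancy share the RNA libraries, and footprints and occupancy the footprint libraries, so these overlaps come from tests that are not independent. Genes that rose in RNA (608 tested in both assays, median RNA 0.43) had a median footprint change of 0, and genes that fell in RNA (133, median -0.48) had one of -0.33. Across the 15231 genes, which are not independent replicates, RNA and footprint changes correlated with a Pearson r of 0.32 and a Spearman rho of 0.25. The RNA and footprint libraries of a pool come from the same hearts. Pearson r was 0.17 without WT pool 2, 0.042 without CM-KO pool 1 and 0.11 without both CM-KO pools that held Y-linked reads.

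The 5′ untranslated region (UTR) was examined because the series concerned structured mRNAs. The quintile of genes with the highest GC content over up to 200 bases before the start codon (2722 genes, 74.0 to 95% GC) had a median occupancy change of -0.12, against 0.02 for the other genes (camera adjusted p = 2.4e-12, and adjusted p = 0.743 with an estimated correlation). The quintile with the most stable predicted folding per base had a median of -0.13 (camera adjusted p = 2.4e-12, and adjusted p = 0.743 with an estimated correlation). Of 126 lower-occupancy genes with a usable 5′ UTR, 78 (61.9%) lay in the top GC quintile, and 32 lay in the top quintile by coding GC. The Spearman correlation across genes was -0.22 for 5′ UTR GC, 0.23 for folding energy, -0.23 for intron length, -0.13 for coding length, -0.12 for 5′ UTR length, -0.11 for coding GC and -0.06 for 3′ UTR length. The top quintile of intron length had a median occupancy change of -0.095 against 0.02 for the other genes (unadjusted camera p = 9e-04, and 0.47 with an estimated correlation). It held 14 of the lower-occupancy genes. Among the 14271 genes tested in RNA with a usable 5′ UTR, the top GC quintile (2855 genes) had a median RNA change of 0.09 and held 303 of 602 higher genes (50.3%; camera adjusted p = 4.59e-11, and adjusted p = 0.283 with an estimated correlation), and among the 13617 tested in footprints it (2724 genes) had a median of -0.04 (camera adjusted p = 0.0907). The occupancy median of the top GC quintile was -0.04 without CM-KO pool 1, -0.07 without WT pool 1 and -0.08 without CM-KO pool 3. For the quintile with the most stable folding it was -0.041, -0.063 and -0.075 in the same order, and -0.171 without WT pool 3. The median of all genes tested moved as well. It was -0.013 with all pools, 0.064, 0.04 and 0.04 in that order, and -0.055 without WT pool 3. These shifts of the quintile medians are therefore not changes of the GC or folding pattern alone.

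**Figure D4:**
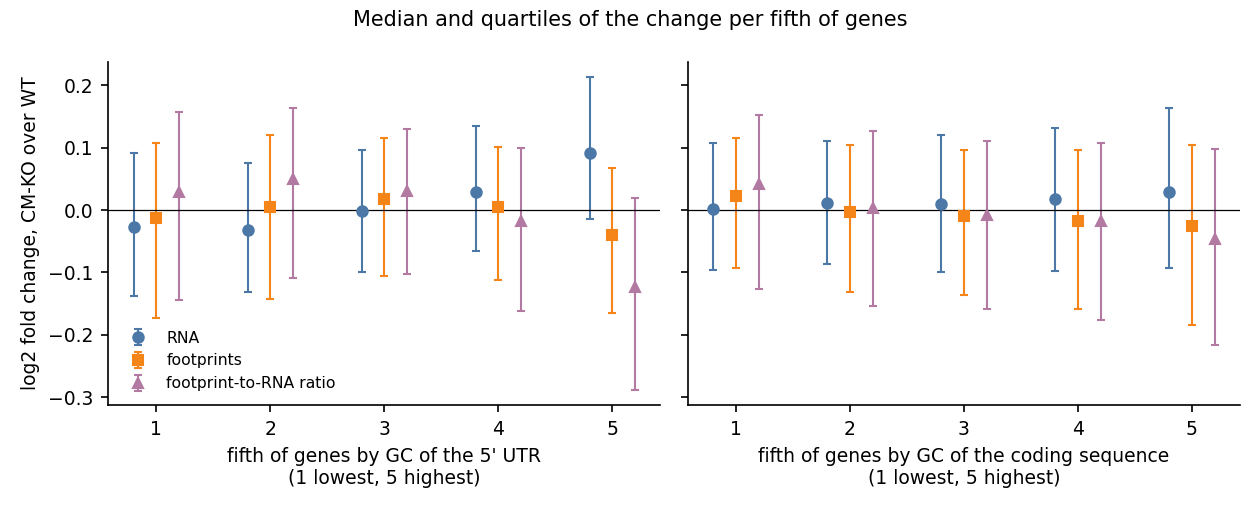
Median log2 fold change (CM-KO over WT; bars from the lower to the upper quartile) of RNA, footprints and footprint-to-RNA ratio in quintiles of the 13606 genes with a usable 5′ UTR, by GC content of the 5′ UTR (left) and of the coding sequence (right). The quintile with the highest 5′ UTR GC had medians of 0.09 in RNA, -0.04 in footprints and -0.12 in the ratio.

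The 6 genes with the largest falls in occupancy had 5′ UTRs of 66.3 to 85.2% GC, read like all values here over at most the 200 bases before the start codon, and 3 of them (Irx1, Bmt2 and Rhod) lay in the top GC quintile. In Rcor2 the 5′ UTR lies on chromosome 19 at 7245592 to 7246326 (735 bases in 1 exon, forward strand). Its last 200 bases have 72.5% GC and a predicted folding energy of -0.478 kcal/mol per base, and its last 40 bases before the start codon are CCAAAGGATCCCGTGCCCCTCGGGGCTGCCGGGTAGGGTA. The 5′ UTR of Irx1 (chromosome 13, 72111608 to 72111848, reverse strand, 241 bases, 79.5% GC in the last 200) ends in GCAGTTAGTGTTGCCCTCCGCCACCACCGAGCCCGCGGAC. The last 200 bases of the 5′ UTR have 70.0% GC in Ryr2 (538 bases in all) and 79.0% GC in Atp2a2 (664 bases in all), while Ccnd2 (52.5% GC) and Trp53inp1 (47.5% GC) had lower occupancy with the lowest 5′ UTR GC of the 20 named genes.

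Of 8 mitochondrially encoded genes tested for occupancy edgeR called 0 over all genes, with 7 higher at an unadjusted p under 0.05 and 1 higher in DESeq2. Adjusted over the list alone 7 were higher, and the median change of the footprint-to-RNA ratio was 0.66 (camera adjusted p = 3.52e-11, and adjusted p = 0.389 with an estimated correlation), with 0.68 for mt-Cytb (adjusted p = 0.191) and 0.63 for mt-Nd1 (adjusted p = 0.154). Erythroid markers had a ratio median of 0.23 (camera adjusted p = 4.62e-05, and adjusted p = 0.955 with an estimated correlation).

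**Figure D5:**
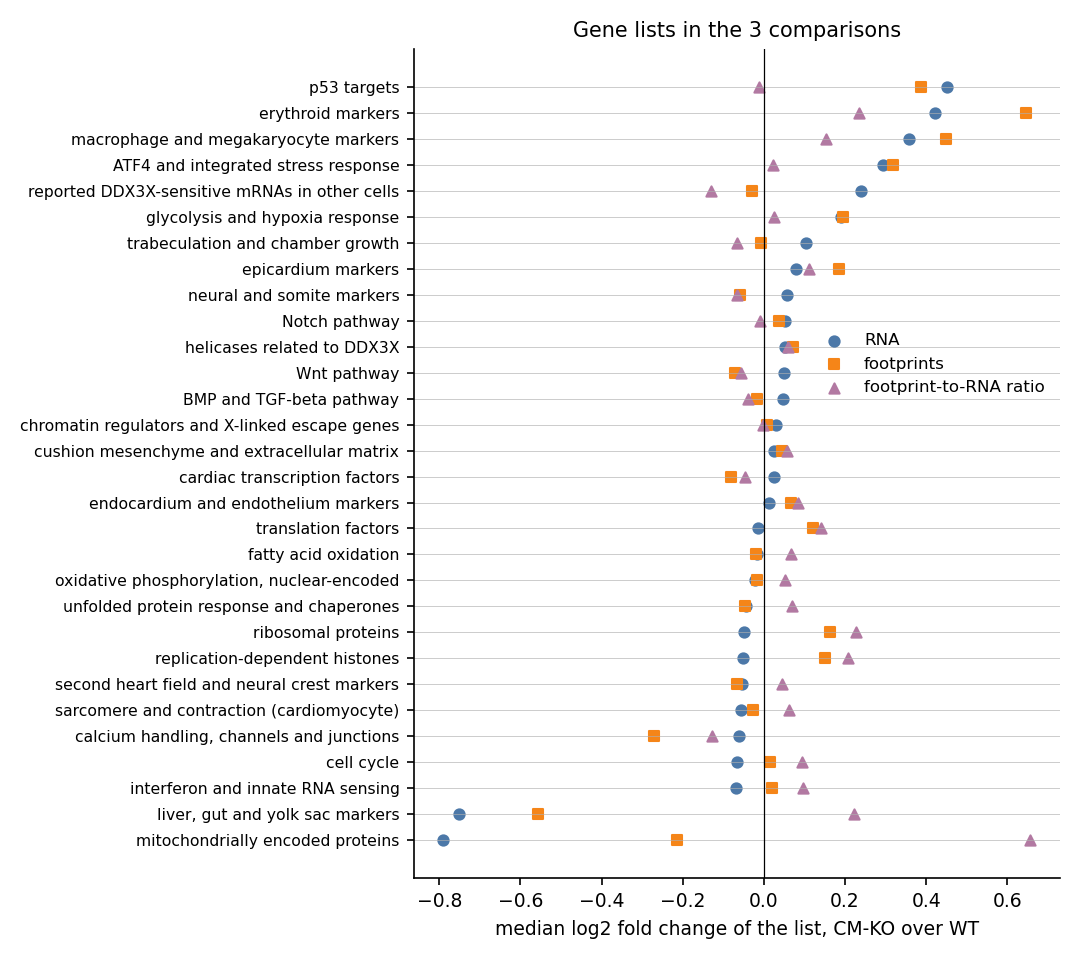
Median log2 fold change (CM-KO over WT) of each tested gene list in RNA (circles), footprints (squares) and the footprint-to-RNA ratio (triangles). The p53 targets had medians of 0.45 in RNA, 0.39 in footprints and -0.01 in the ratio, and the mitochondrially encoded genes -0.79, -0.21 and 0.66.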

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

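The tests of explanations in this part were chosen after the result was seen, and leaving out both CM-KO pools with Y-linked reads was added after seeing the data.

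Among genes blank in all WT pools, and so outside the comparisons, 6 reached at least 50 counts in a CM-KO library, and 3 of them are Y-linked. In the RNA library of CM-KO pool 1 Uty had 174 counts, Eif2s3y 86 and Kdm5d 86. CM-KO pool 2 gave 108, 53 and 39 counts for the same genes, while in pool 3 Uty had 11 and the others were blank. The prolactin-family placental genes Prl7a1 and Prl3b1 had 64 and 60 counts in the footprint library of CM-KO pool 2. Prl7a1 was filled in every CM-KO pool, with 18, 17 and 8 RNA counts in pools 1 to 3 and 11 footprint counts in pools 1 and 3. Prl3b1 had 12 and 11 RNA counts in CM-KO pools 1 and 2 and 10 footprint counts in pool 1, and was blank in pool 3. Sap30bpos, an RNA named as antisense to Sap30bp, had 58 counts in the footprint library of CM-KO pool 1.

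In these pools labelled as female, reads shared with the X-linked copy Kdm6a are argued against as the source of Uty RNA, because at the rate per Kdm6a read of CM-KO pool 1 the WT RNA libraries would hold 157.6 to 222.5 Uty counts, and all 3 were blank. Ddx3y footprints (15, 21 and 19 counts in WT) do hold such a background, which at the highest WT rate per Ddx3x read gives 18.7, 23.2 and 29.4 counts in CM-KO pools 1 to 3, so it covers the 24 counts of pool 3 but is argued against as the whole source of the 69 and 75 in pools 1 and 2. The ratios of pool 1 to pool 2 in RPM of Ddx3y, Uty, Eif2s3y and Kdm5d were 1.53 to 2.10 in RNA (chi-square p = 0.549) and 0.82 to 1.72 in footprints (chi-square p = 0.0758, and 0.0323 without Ddx3y), with Kdm5d the highest in RNA and the lowest in footprints. Male hearts in both pools may be the source but cannot be told apart from other male tissue or RNA carried into them, since single pools can differ by more than counting error, carcasses were genotyped for Sry, which would remove male embryos, and Xist RNA was 401 and 287 CPM in these pools against 319 to 411 in WT, and no biological explanation was tested. Without both pools, 126 RNA genes were called, 125 of them among the 750, with 5 occupancy genes, all among the 128, the lone CM-KO pool being assumed to vary like the WT pools.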

How the results depend on the processing

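No called gene changed sign under any setting, and the counts depended on the pools. RNA calls (750) ranged from 207 to 783 with each pool left out in turn, footprint calls (35) from 1 to 94 and occupancy calls (128) from 9 to 113, with fewer pools in each fit. With the fold threshold the counts were 287, 9 and 30. DESeq2 gave 970 RNA genes, 172 footprint genes (57% higher against 37.1%) and 59 occupancy genes. All 12 libraries in one model gave 250 RNA and 80 footprint genes. Upper quartile scaling gave 60 footprint and 248 occupancy genes, the stricter filter 54 and 282, and RLE scaling 41 occupancy genes, no count filter 29, and limma on log2 ratios 3. Of the settings added after seeing the data, leaving out both CM-KO pools with Y-linked reads gave 126, 54 and 5, and the Afp covariate 286, 5 and 39. Blocks changed counts as well: the block by replicate number gave 367 RNA and 203 footprint genes (58.1% of the latter higher), and the block by pool 226 occupancy genes. Replicate numbers were not taken to pair WT with CM-KO pools: deviations of same-numbered pools correlated by -0.36 to 0.24 in RNA and by 0.09 to 0.41 in footprints, which does not exclude pairing in footprints. The RNA change of Ddx3x passed the threshold with DESeq2 (-0.35, adjusted p = 0.00589), upper quartile scaling (-0.39, 0.0408), the stricter filter (-0.36, 0.0449) and 1 pool left out (range -0.48 to -0.27). The correlation of RNA and footprint changes ranged from 0.042 to 0.417 with a pool left out and was 0.11 without both pools with Y-linked reads. With an estimated correlation the occupancy medians of -0.12 (top quintile of 5′ UTR GC), -0.13 (most stable folding) and 0.036 (least stable folding) had adjusted p = 0.743. The least stable quintile also missed the threshold without both pools with Y-linked reads (0.068) and in some fits with a pool left out (range -0.001 to 0.115). The longest 5′ UTRs passed with the stricter filter (-0.02, adjusted p = 0.0437). The RNA median of the liver, gut and yolk sac list turned to 0.068 without both pools with Y-linked reads and that of the histones to 0.014 without WT pool 3. The other values were counted once for each list or gene in each setting, so 1 gene can count many times. Of the list values 66 lost and 57 gained a call, while 1247 did not change. Of the values of named genes 464 lost and 113 gained a call, while 2669 did not change. Beyond the pools left out, the cause was not tested. At the depth and spread of these libraries (footprints from 7.31 M counts), the tests recovered 26% of simulated footprint changes of 0.5. For occupancy they recovered 13% of changes of 0.5 that were simulated in footprints alone, unlike most real calls, and depth alone was not varied.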

Other observations

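The tests of explanations in this part were chosen after the result was seen, whereas the gene lists and their tests were fixed before the data were examined.

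Most genes of the translation machinery had footprint changes above 0, but single genes rarely passed. Called in footprints by edgeR were 0 of 77 ribosomal protein genes, 0 of 54 translation factors and 0 of 26 helicases related to DDX3X, against 3, 3 and 1 higher in DESeq2. At an unadjusted p under 0.05 edgeR had 13, 11 and 5 higher and 0, 1 and 0 lower. Of the 77 ribosomal protein genes 69 had footprint changes above 0, with a median of 0.16 (camera adjusted p = 1.8e-10, and adjusted p = 0.475 with an estimated correlation). They had a median ratio change of 0.23 (camera adjusted p = 5.91e-15, and adjusted p = 0.57 with an estimated correlation), while their RNA median was -0.05 (camera adjusted p = 0.0251, and adjusted p = 0.856 with an estimated correlation). The RNA call ended without WT pool 1 (adjusted p = 0.354), WT pool 3 (0.121), CM-KO pool 1 (0.162) or CM-KO pool 3 (0.0595). Rpl12, a protein of the large subunit, had a footprint change of 0.65 (adjusted p = 0.152). Among the translation factors 50 had footprint values above 0 (median 0.12, camera adjusted p = 1.72e-10, and adjusted p = 0.475 with an estimated correlation), with 0.43 for the initiation factor gene Eif5 (adjusted p = 0.0732) and 0.41 for the helicase gene Eif4a1 (adjusted p = 0.124), while Eif5 RNA rose by 0.59 (adjusted p = 0.00104). Of the 26 helicases 25 had footprint values above 0 (median 0.07, camera adjusted p = 4.58e-05, and adjusted p = 0.475 with an estimated correlation). They include Ddx3y, with 69 and 75 footprint counts in CM-KO pools 1 and 2, which held Y-linked reads, and 24 in pool 3. Eif4a1, Eif4a2 and Eif4a3 are members of both this list and the translation factors. Replication-dependent histone genes had a footprint median of 0.15 over 57 genes (camera adjusted p = 3.97e-07, and adjusted p = 0.817 with an estimated correlation, or a median of 0.036 and 0.0891 without CM-KO pool 3) and a ratio median of 0.21 (camera adjusted p = 6.34e-10, and adjusted p = 0.955 with an estimated correlation).

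Lists of other cell types and processes gave few calls of single genes. Of 17 macrophage and megakaryocyte markers 0 were called in footprints by edgeR (6 higher at an unadjusted p under 0.05, and 3 higher in DESeq2), with a median of 0.45 (camera adjusted p = 4.02e-11, and adjusted p = 0.303 with an estimated correlation), with 1.05 for the platelet factor gene Pf4 (adjusted p = 0.0732). Of the 13 epicardial markers 1 was called in footprints, and all had values above 0 (median 0.19, camera adjusted p = 2.57e-06, and adjusted p = 0.475 with an estimated correlation), and the called keratin gene Krt8 rose by 0.50 in footprints (adjusted p = 0.0315) and by 0.40 in RNA (adjusted p = 0.0349). Of the 26 endocardial and endothelial markers 0 were called by edgeR in RNA (2 higher and 3 lower at an unadjusted p under 0.05, and 1 higher in DESeq2) or in footprints (2 higher at an unadjusted p under 0.05, and 0 in DESeq2). They had medians of 0.01 in RNA (camera adjusted p = 0.863) and 0.07 in footprints (camera adjusted p = 0.159, and adjusted p = 0.941 with an estimated correlation). At the preset correlation the footprint median passed with 0.13 without CM-KO pool 1 (adjusted p = 0.00047) and 0.16 without WT pool 3 (adjusted p = 0.000495). Cell cycle genes had an RNA median of -0.07 (camera adjusted p = 0.0145, and adjusted p = 0.856 with an estimated correlation), and Ube2c, a ubiquitin-conjugating enzyme gene of mitosis, fell by 0.31 (adjusted p = 0.0226). That list call ended without WT pool 3 (adjusted p = 0.514), CM-KO pool 2 (0.15) or CM-KO pool 3 (0.104). Glycolysis and hypoxia genes had a footprint median of 0.20 (camera adjusted p = 0.00428, and adjusted p = 0.941 with an estimated correlation), which missed the threshold without WT pool 3 (0.11, adjusted p = 0.133) or CM-KO pool 3 (0.02, adjusted p = 0.458), while Pdk1 fell by 0.59 in footprints (adjusted p = 0.0395).

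For the lower ratio of genes with GC-rich 5′ UTRs, GC bias between RNA libraries is argued against as the whole cause, since the odds of a lower ratio in the top quintile of 5′ UTR GC stayed 6.72-fold (95% interval 4.64 to 9.72) within quintiles of coding GC, although a bias limited to fragments of the 5′ UTR was not tested. The ratio also fell with intron length across all genes (Spearman -0.23). Intron reads of unspliced RNA would act through the RNA libraries. The trend lay more in footprints (Spearman -0.171) than in RNA (0.071). These correlations come from separate fits, and the share of such reads in the trend was not tested. As the whole cause of the GC pattern such reads are argued against, because 11.1% of the calls (6.2 to 17.9%) lay in the top quintile of intron length, and in the bottom quintile of intron length the top GC quintile still lay -0.198 from the other genes (bootstrap interval -0.225 to -0.169, and -0.146 over all genes). For these calls a loss of footprints alone is argued against because in 81.1% of them (73.2 to 87.5%) the RNA rise exceeded the footprint fall. The calls were chosen by the ratio in the same libraries, so they are not an independent sample. In the whole top GC quintile, chosen without the ratio, the medians were 0.09 in RNA and -0.04 in footprints. All intervals in this paragraph take genes as units with the pools held fixed. They do not cover spread between pools, so the arguments hold for these pools only. The intron length trend itself, unspliced RNA counted in exons, GC bias of fragments outside the coding sequence, the part of each transcript that was counted and an effect of the deletion on these mRNAs stay open, the last as untested.

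Of 26 erythroid markers, all detected in hearts of both genotypes, 11 were called higher in RNA and 1 in footprints, and the list call was lost with an estimated correlation (adjusted p = 0.434 and 0.221). The embryonic globin gene Hbb-y stood at 4360 ± 1040 CPM in WT RNA and 5860 ± 923 in CM-KO, and at 20300 ± 2980 and 31900 ± 3570 in footprints (mean ± SD, n = 3). For these pools, a lower share of cardiomyocytes as the whole cause is argued against. Endothelial markers had a footprint median of 0.066 (bootstrap interval over list members 0 to 0.10) against 0.65 (0.62 to 0.68) for erythroid markers, and at most 0.157 for the former with a pool left out. Epicardial markers stood at 0.19 (0.04 to 0.27) and cushion genes at 0.04 (-0.06 to 0.14), while macrophage and megakaryocyte markers, also of blood lineages, stood at 0.45 (0.38 to 0.71). These intervals resample list members with the pools held fixed, so they do not cover spread between pools. Erythroid footprint medians of single pools deviated by -0.51 to -0.09 in WT and by 0.12 to 0.58 in CM-KO. Those of endothelial markers overlapped (-0.22 to 0.15 in WT and -0.18 to 0.23 in CM-KO). More blood in the CM-KO pools remains a candidate cause that cannot be told apart from a change within erythroid cells, as the ratio of erythroid markers changed by 0.23 with calls that differ between the preset and the estimated correlation.

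The 6 pools can be split 3 against 3 in 10 ways, which cannot give a share under 0.05. As many genes as the real split called were found in 1 of the 10 splits, the real split itself, in each comparison. It called 750 RNA genes with 2 in the highest other split, 35 footprint genes with 28, and 128 occupancy genes with 0. The split with 28 footprint genes set WT pool 1 and CM-KO pools 1 and 2 against the other pools, and all 28 were higher in WT pools 2 and 3 and CM-KO pool 3. Of these 28 genes 11 belong to the liver, gut and yolk sac list, of which 16 members were tested, and the 35 genes called between genotypes held 0 of the 28. Nepn, a proteoglycan gene chosen after its values were seen, had 16, 25 and 92 RNA counts in WT pools 1 to 3 and was blank in all CM-KO pools.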
